A study of Homo sapiens with 6 samples.

How the data were processed

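Gene expression was measured on 6 Affymetrix 3' expression arrays carrying 54675 probe sets each. The cells were CaSki, an established human cervical squamous carcinoma line that carries integrated papillomavirus DNA. Per the labels' protocols, cells were grown with recombinant TGF-β1 at 2 ng/mL or in medium without it, total RNA was extracted with the RNeasy method, and biotinylated cRNA was made for hybridisation. Each group had 3 arrays, numbered 1 to 3 in the titles. The labels do not say whether the 3 came from separate cultures, and the duration of treatment is not given in the sources used here, so the p-values measure the spread between these samples, which may be technical.

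The deposited values are log2 expression estimates, 1 per probe set and array. Per the submitters' processing notes, they were made with Affymetrix Expression Console and RMA, a method that subtracts background, equalises the distribution of probe intensities between arrays and combines the probes of a probe set. Versions and options are not given in the sources used here. The log2 scale was inferred from the values, which ran from 1.57 to 14.5 on the 6 arrays with medians between 4.15 and 4.18. Scanner files were not used here, so no detection call or background level per probe was available, and RMA is known to compress differences of dim probe sets. Arrays have no read depth, and the precision is limited by the 3 arrays per group.

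Gene names came from the platform annotation of the probe sets, with symbols taken through the gene number from a RefSeq table of assembly GRCh38.p14, which was used for names only. Of the 54675 probe sets, 62 were controls, 41091 carried 1 gene symbol, 1801 carried several, and 11721 had no name here. Updating changed 0 symbols, and 54 probe sets had a gene number without a RefSeq row and kept their annotated symbol. Probe sets with 1 symbol covered 19775 genes, of which 10523 had more than 1 probe set. Each gene was represented by its probe set with the highest mean over all 6 arrays. Among called genes named here, ATF3, CALD1, DUSP1, JAG1, SOX4, TGFB1, TGFB2 and TNFRSF19 had a dimmer probe set above the array median whose difference had the opposite sign and did not pass. No genome positions are given, since the annotation names no build.

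Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), on the deposited values without a filter, and p-values were adjusted by the Benjamini-Hochberg method over the 19775 genes. A gene was called changed at an adjusted p below 0.05. Differences are treated minus untreated on the log2 scale with the moderated standard error of limma. Gene lists were tested with camera at its preset inter-gene correlation of 0.01 and adjusted over 26 lists. The camera calls were repeated with the correlation estimated from the arrays. The replicate number was not used as a block. Deviations of same-numbered arrays from their group means correlated at 0.20, 0.06 and 0.09. Of these, 2 lay below the minimum of 0.1 used in this check, although 5 of the 6 arrays correlated best with their own number. The design fixed beforehand had no block, and pairing by number remains possible.

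The groups, the tests, the 26 lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls among called genes whose treated and untreated values did not overlap, a panel of TGF-β and epithelial-mesenchymal transition (EMT) genes, and up to 4 members of each list with the smallest p. Of 651 list genes, 610 had a probe set with a single name, and the other 41 were not analysed here. JUP, NRP1, PLAT, INHBA, LTBP4, HSPA5, DUSP5, IL32, LIF, IL11, IL6, MYOF, KRT16, SERPINB3, SLC2A1 and CCND1 are named outside the rule, chosen after their values were seen. Alternatives were a repeated quantile normalisation, median centring, 2 filters on dim probe sets, the mean of a gene's probe sets, exclusion of probe sets whose suffix marks shared sequence, a trended robust variance, array weights, a block for the replicate number, the removal of each array in turn, other list tests, tests of single probe sets and limma's treat against a fold of 1.2. When an array was removed, the representative probe set was chosen again from the remaining arrays. Such a fit has fewer samples, so a lost call can reflect this as well as the array. Removal of both arrays numbered 1 and a covariate for the 3' to 5' signal were added after seeing the data.

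The fit was tested on simulated data made from the means and spreads of the 19775 genes in this comparison. With 100 genes changed by a fold of 1.5 and 100 changed by a fold of 2, it recovered 67% of the first and 92% of the second, and 5.36% of its calls were false. With no gene changed, it made 0 calls and camera called 0 lists. The simulated genes varied independently of each other, so these runs could not test how correlation between genes affects the list calls. The runs also held no effect of array number and far fewer changed genes than the 1680 called in the real comparison. The recovered and false shares may therefore differ in the real data.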

Results

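The study asked how expression in CaSki cervical squamous carcinoma cells differed with recombinant TGF-β1 at 2 ng/mL, and whether genes of the TGF-β pathway were among those that differed. There were 3 untreated and 3 treated arrays, each with 54675 probe sets. Arrays of 1 group correlated with r between 0.994 and 0.996 over all probe sets, and arrays of different groups with r between 0.992 and 0.993. The first principal component held 51.2% of the variance and separated the groups, with the untreated arrays between -17.3 and -16.1 and the treated arrays between 16.0 and 17.7. The second held 17.9% and set the array numbered 1 apart in both groups, at 8.34 for the untreated and 17.7 for the treated array. These 2 arrays also had the highest 3' over 5' signal of the GAPDH and ACTB control probe sets, a sign of RNA quality, at 1.19 and 1.15 on the log2 scale against 0.690 to 0.863 on the other 4. The mean 3' over 5' signal was 0.859 ± 0.256 (SD, n = 3) in treated and 0.939 ± 0.219 (SD, n = 3) in untreated samples, a difference of -0.08 (exact two-sided permutation test, p = 0.5, the smallest possible being 0.1). This difference ran from -0.227 to 0.0432 when single arrays were left out. The 9 bacterial and phage spike-in probe sets read 0.0893 to 0.41 higher (log2) on the treated arrays, and 0.0301 to 0.183 higher without untreated array 3, which had the lowest of these signals.

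Of 19775 genes 1680 differed between TGF-β1-treated and untreated cells, of which 796 were higher and 884 lower with treatment (limma, adjusted p below 0.05). Which side was larger differed between settings. Rises were 47.4% of the changed genes, but 51.2% after repeated quantile normalisation and 57.0% without both arrays numbered 1. They were 41.9% with a trended robust variance, 43.3% among genes above the median level and 43.5% with the 3' to 5' covariate. Without single arrays they were 50.5% to 58.9%, except 47.8% without treated array 3. Large changes were mostly rises: among the 124 genes that changed at least 2-fold, 94 rose and 30 fell. The largest rise was that of ODAPH, which encodes an enamel matrix phosphoprotein, from 5.11 ± 0.158 to 8.92 ± 0.103 (log2, SD, n = 3), 14.1-fold with an adjusted p of 3.6e-06. It was followed by the long non-coding RNA LINC02551 at 7.48-fold, SCG5, a secretory granule chaperone, at 7.40-fold, XYLT1, which starts glycosaminoglycan chains, at 7.35-fold, and the small GTPase RHOB at 6.17-fold. COL4A1 rose 4.88-fold, PDZK1, a scaffold protein, 4.79-fold, LTBP2, a latent TGF-β binding protein family member, 4.43-fold, the matricellular gene CCN2 4.29-fold and the transcriptional regulator MN1 4.28-fold. The 2 LINC02551 probe sets differed in size, at 2.90 and 0.29 on the log2 scale, and so did the 2 XYLT1 probe sets, at 2.88 for the suffixed and 1.14 for the other. Untreated levels of LINC02551, SCG5, XYLT1 and PDZK1 (3.985, 3.394, 3.946 and 4.136) lay below the array medians, so their folds and their order are uncertain.

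The largest fall was that of SERPINB13, a serpin of squamous epithelium, which was 5.46-fold lower in treated cells (6.07 ± 0.0429 to 3.62 ± 0.222, log2, SD, n = 3, adjusted p = 1.9e-05). MMP7, the protease matrilysin, was 4.01-fold lower, the neutrophil chemokine CXCL8 3.90-fold lower, HS3ST1, a heparan sulfate sulfotransferase, 3.60-fold lower and the tight junction gene CLDN1 3.16-fold lower. CYP1B1, a cytochrome P450, was 3.12-fold lower, TTYH1 2.81-fold, FGFBP1, which carries fibroblast growth factors, 2.78-fold, XK 2.77-fold and SHOC1 2.67-fold lower. For SERPINB13, a second probe set fell by 2.21 (log2) while 2 probe sets without shared-sequence suffix, at levels of 3.66 and 3.58, differed by 0.04 and 0.46 without passing. The other HS3ST1 probe sets, at levels of 4.44 and 4.33, differed by -0.20 and -0.47 without passing. Treated levels of SERPINB13, TTYH1 and XK (3.624, 3.806 and 3.908) lay below the array medians, so the size of these falls is uncertain. Of all genes tested, 29.2% had treated and untreated values that did not overlap, against 10% by chance. The number of changed genes was lower whichever single array was left out, where fewer samples enter the fit. It was 878, 766 and 772 without untreated array 1, 2 or 3, and 1319, 883 and 933 without treated array 1, 2 or 3. It was 628 without both arrays numbered 1, while the number changed at least 2-fold stayed between 122 and 130 in these 7 fits.

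**Figure D1:**
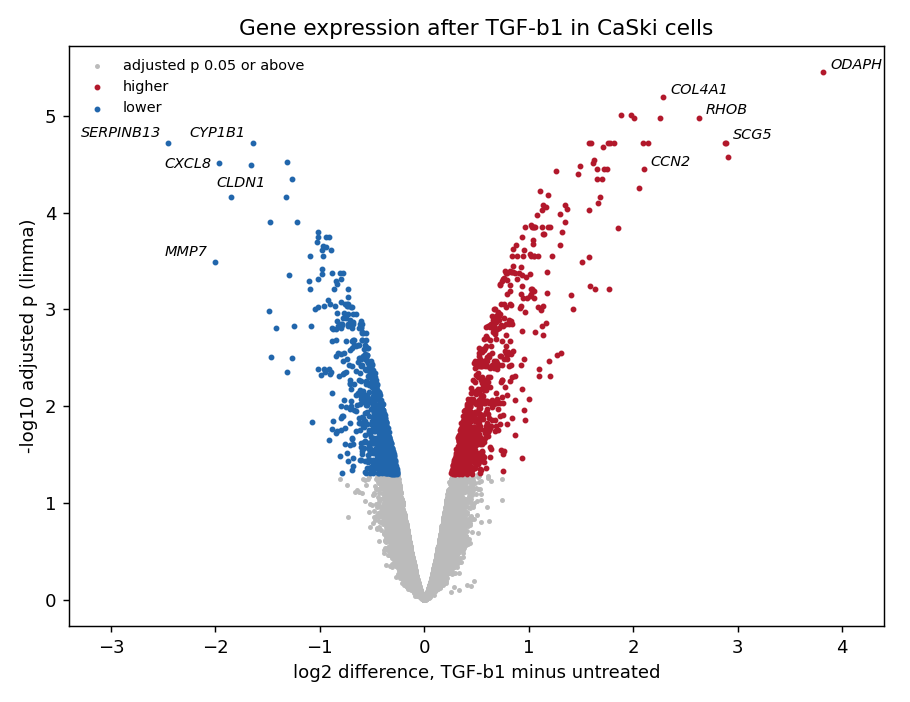
Log2 difference (TGF-β1 minus untreated, horizontal axis) against -log10 of the limma adjusted p (vertical axis), 1 point per gene for 19775 genes. Red points are the 796 genes that rose and blue points the 884 that fell; ODAPH lies farthest right at 3.82 and SERPINB13 farthest left at -2.45.

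Direct targets and feedback genes of TGF-β/SMAD signalling rose as a group. Of 24 measured members 15 rose, 0 fell and 9 did not pass (17 rose and 1 fell when adjusted over the list alone), with a median difference of 0.55 (log2). PMEPA1, a feedback inhibitor of the pathway, rose 3.94-fold, and RHOB, LTBP2 and CCN2 rose as above. SMAD7, the inhibitory SMAD, rose 3.17-fold from 4.99 ± 0.191 to 6.66 ± 0.0444 (log2, SD, n = 3, limma adjusted p = 7.9e-05). The list was called by camera (adjusted p = 1.6e-17, and adjusted p = 0.0189 with an estimated correlation). Of the 15 rises, 12 passed without any single array.

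Ligands, receptors and signal-transducing SMADs moved in both directions. Of 26 measured members 5 rose and 2 fell (6 and 3 when adjusted over the list alone), and the list was not called (camera adjusted p = 0.80; median -0.02, mean 0.02, tested direction up). The activin subunit gene INHBB was 2.49-fold lower and SMAD3 was 1.64-fold lower (difference -0.71 ± 0.08, SE, adjusted p = 0.0013). The BMP receptor BMPR2 rose 1.91-fold and TGFB2 rose by 0.68 on the log2 scale. INHBA, TGFB1 and LTBP4 were the other rises, at 1.62-fold, 1.68-fold and 1.31-fold. The TGFB1 call was lost without untreated array 3 (adjusted p = 0.0562), and its second probe set, at a level of 4.33, differed by -0.08. The LTBP4 call was lost without 5 of the 6 arrays in turn (adjusted p up to 0.114). TGFBR1, TGFBR2, SMAD2 and SMAD4 did not pass, with differences of 0.02, -0.02, -0.07 and -0.09 and 95% intervals that lay between -0.30 and 0.18.

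Among 15 targets of the BMP branch, NOG, a secreted BMP antagonist, rose 1.95-fold, while ID1 was 2.02-fold and ID4 1.29-fold lower. ID1 and ID4 encode inhibitors of helix-loop-helix factors. The ID4 call was lost without 5 of the 6 arrays in turn (adjusted p up to 0.124), and DLX2 did not pass (0.34, adjusted p = 0.0628). The list was not called (camera adjusted p = 0.29), and 3 members rose and 2 fell when adjusted over the list alone.

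Of the transcription factors that drive EMT, 2 of 16 measured members rose, SNAI2 and SOX4, and 0 fell, also when adjusted over the list alone. SNAI2, which encodes Slug, rose 2.11-fold from 9.78 ± 0.0636 to 10.9 ± 0.0304 (log2, SD, n = 3, limma adjusted p = 1.1e-04), and SOX4 rose 1.95-fold. SNAI1 differed by 0.20 ± 0.09 (SE, adjusted p = 0.21), TWIST1 by -0.08, and ZEB1 and ZEB2 by 0.00 and 0.01 at levels of 3.33 and 3.39, below the array median. Their dimmer probe sets differed by 0.00 to 0.38 for ZEB1 and by -0.13 to 0.53 for ZEB2, without passing. SOX9 and TCF4 did not pass, with differences of -0.18 and 0.45. Only 7 of the 16 lay above the array median. Camera called the list (adjusted p = 0.0308, and adjusted p = 0.15 with an estimated correlation), and the call was lost without untreated array 2 or 3 or treated array 1 (adjusted p = 0.0505, 0.0556 and 0.0562) and without both arrays numbered 1 (adjusted p = 0.0532).

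Mesenchymal and contractile genes were the list with the highest median, 0.552 (log2), close to the 0.545 of TGF-β/SMAD targets. Without both arrays numbered 1 the order turned, at 0.525 and 0.599. Of 22 measured mesenchymal and contractile genes 16 rose and 1 fell (16 and 2 when adjusted over the list alone). CALD1, which encodes the actin-binding protein caldesmon, rose 3.06-fold, LMCD1 2.98-fold, the tropomyosin gene TPM1 2.27-fold and CDH2, which encodes N-cadherin, 2.18-fold (8.35 ± 0.00863 to 9.47 ± 0.0774, log2, SD, n = 3). VIM, the mesenchymal intermediate filament, rose 1.63-fold. The 1 fall was NRP1, a semaphorin and growth factor co-receptor, 1.82-fold lower. Without untreated array 1, 2 or 3 its other bright probe set becomes the representative, at 1.150-fold, 1.148-fold and 1.152-fold lower, and the call is lost (adjusted p up to 0.36), while the first probe set alone still differs by -0.828, -0.9003 and -0.8574 (log2). The VIM call was lost without untreated array 1 or 3 or treated array 2 or 3 (adjusted p = 0.0656, 0.0619, 0.0625 and 0.0599). As a list they were called by camera (adjusted p = 9.6e-12, and adjusted p = 0.0189 with an estimated correlation). Of the 16 rises, 10 passed without any single array.

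Genes of epithelial adhesion and identity were lower in part. Of 29 measured members 8 fell and 1 rose (12 and 3 when adjusted over the list alone), with a median of -0.13 (log2). CLDN1 fell 3.16-fold, the epithelial transcription factor ELF3 was 2.13-fold lower, EPCAM 1.62-fold lower and the tight junction gene OCLN 1.41-fold lower. The 1 rise was JUP, which encodes plakoglobin, at 1.31-fold (adjusted p = 0.0435, lost without 5 of the 6 arrays in turn, adjusted p up to 0.142). CDH1, which encodes E-cadherin, stood at 10.3 ± 0.0848 in untreated and 10.4 ± 0.160 in treated cells (log2, SD, n = 3), a difference of 0.06 with a 95% interval from -0.17 to 0.28 (limma adjusted p = 0.78). The list was called by camera (adjusted p = 0.0067, and adjusted p = 0.39 with an estimated correlation), and the call was lost without treated array 1 (adjusted p = 0.0550). Of the 8 falls, 5 passed without any single array. Without both arrays numbered 1, 4 members fell and the list was not called (adjusted p = 0.0613).

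**Figure D2:**
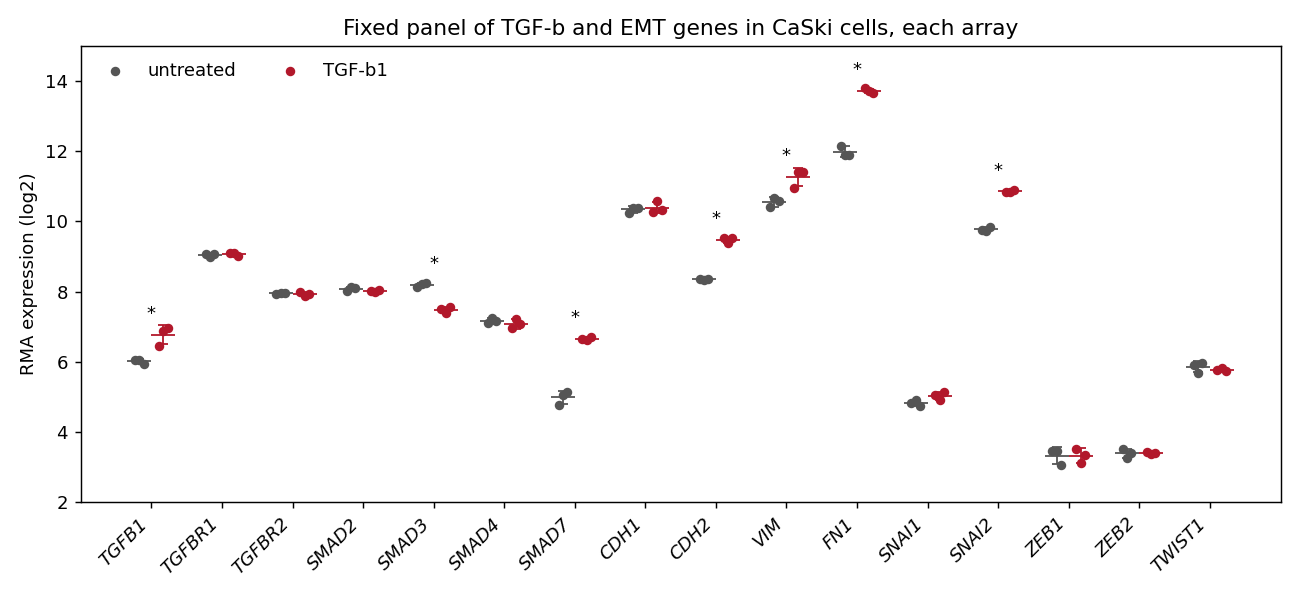
RMA expression (log2, vertical axis) of 16 TGF-β and EMT genes fixed before the data were examined, with 1 point per array, a horizontal mark for the mean and bars for 1 SD (n = 3); asterisks mark adjusted p below 0.05. TGFB1, SMAD7, CDH2, VIM, FN1 and SNAI2 lie higher in treated cells and SMAD3 lower, while CDH1 overlaps between the groups.

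Genes of the extracellular matrix and of collagen processing rose. Of 43 measured members 14 rose and 0 fell, also when adjusted over the list alone, with a median of 0.19 (log2). Besides COL4A1, FN1, which encodes fibronectin, rose 3.36-fold from 11.98 ± 0.155 to 13.7 ± 0.0586 (log2, SD, n = 3), COL5A1 3.31-fold and COL4A2, the partner chain of COL4A1 in basement membranes, 3.25-fold. Camera called the list (adjusted p = 1.4e-09, and adjusted p = 0.0189 with an estimated correlation), and 11 of the 14 rises passed without any single array. Of 14 fibroblast markers, FAP, a cell-surface protease, rose 1.85-fold and PDGFRL was 1.51-fold lower, also when adjusted over the list alone; DCN and TCF21 differed by 0.27 and 0.28 without passing, and the list was not called (camera adjusted p = 0.49). Of 15 endothelial and immune markers, KDR rose 1.23-fold and CDH5 was 1.33-fold lower, also when adjusted over the list alone, at untreated levels of 2.67 and 3.32, below the array median, and the calls were lost without 6 and 5 of the 6 arrays in turn (adjusted p up to 0.110). CSF1R and CD163 differed by 0.36 and 0.31 without passing, and that list was not called (camera adjusted p = 0.56).

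Among matrix proteases and their inhibitors more rose than fell: of 30 measured members 12 rose, 2 fell and 16 did not pass (14 and 2 when adjusted over the list alone). PLAU, the urokinase plasminogen activator, rose 4.17-fold, SERPINE2, a serpin that inhibits it, 3.68-fold, the gelatinase gene MMP2 3.14-fold and ADAM19 3.07-fold, while MMP7 fell as above and PLAT, the tissue plasminogen activator, was 1.47-fold lower. As a list they were called by camera (adjusted p = 3.8e-07, and adjusted p = 0.0697 with an estimated correlation). Of 18 integrins and matrix receptors 6 rose and 1 fell (9 and 2 when adjusted over the list alone). ITGAV rose 1.65-fold, ITGA5, a chain of the fibronectin receptor, 1.64-fold and ITGB5 1.49-fold, while ITGB8 was 1.55-fold lower. That list was called as well (camera adjusted p = 0.0039, and adjusted p = 0.13 with an estimated correlation). Without any single array 7 of the 12 protease rises and 3 of the 6 integrin rises passed.

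Some cell cycle genes were lower in treated cells, mostly by small amounts. Of 35 measured members 10 fell and 1 rose (12 and 1 when adjusted over the list alone), with a median of -0.20 (log2), and the 1 rise was CCND1, which encodes cyclin D1, at 1.36-fold (lost without 4 of the 6 arrays in turn, adjusted p up to 0.0619). The proto-oncogene MYC was 1.96-fold lower (-0.97 ± 0.07, SE, limma adjusted p = 2.2e-04), the replication factor MCM10 1.52-fold lower and the mitotic checkpoint kinases BUB1B and BUB1 1.48-fold and 1.40-fold lower. The list was called by camera (adjusted p = 3.8e-07, and adjusted p = 0.0721 with an estimated correlation). Of the 10 falls, 4 passed without any single array and 5 passed without both arrays numbered 1.

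Among targets of p53 and apoptosis genes, 7 of 20 rose and 1 fell (9 and 2 when adjusted over the list alone). TP53I3, a quinone oxidoreductase, rose 3.52-fold, TP53INP1 3.02-fold and the RNA-binding protein gene ZMAT3 1.76-fold, while the pro-apoptotic PMAIP1 was 1.68-fold lower. The median was 0.07 and the mean 0.30 (log2). Camera called the list (adjusted p = 4.3e-04, and adjusted p = 0.15 with an estimated correlation). Without any single array 5 of the 7 rises passed, and without both arrays numbered 1 there were 3.

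Keratinocyte genes moved in both directions. Of 33 squamous differentiation genes, IVL, which encodes the cornified envelope protein involucrin, rose by 1.58 on the log2 scale, while S100A9 was 1.86-fold, the filaggrin gene FLG 1.51-fold and KLK10 1.26-fold lower (1 rose and 6 fell when adjusted over the list alone). FLG lay at a level of 3.45, below the array median, and its call was lost without untreated array 2 (adjusted p = 0.0523). The KLK10 call was lost without any of the 6 arrays (adjusted p up to 0.148). Of 14 basal keratinocyte genes, 3 rose and 3 fell (3 and 6 when adjusted over the list alone). KRT14 rose 1.71-fold and the transcription factor BNC1 1.62-fold, while KRT15 was 2.45-fold and FABP5 1.38-fold lower. The others were KRT16 at 1.40-fold higher and SERPINB3 at 1.62-fold lower, and each of these 2 calls was lost without 5 of the 6 arrays in turn (adjusted p up to 0.143). Without both arrays numbered 1, each of these 2 lists had 1 rise and 1 fall. Neither list was called (camera adjusted p = 0.29 and 0.49).

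Inflammatory genes moved in both directions. Of 31 measured members 5 rose and 7 fell (5 and 8 when adjusted over the list alone), and the list was not called (camera adjusted p = 0.29). CXCL8 fell 3.90-fold, from 9.97 ± 0.107 to 8.01 ± 0.154 (log2, SD, n = 3), SOD2, the mitochondrial superoxide dismutase, was 2.12-fold lower and the chemokine CXCL2 1.89-fold lower. The other 2 CXCL2 probe sets, at levels of 2.30 and 2.19, differed by 0.12 and -0.07. Of the 7 falls, 4 passed without any single array, and without both arrays numbered 1 there were 3 rises and 4 falls. PTGS2, which encodes cyclooxygenase, rose 3.28-fold. The other rises were IL32 at 1.67-fold, LIF at 1.44-fold, IL11 at 1.38-fold and IL6 at 1.23-fold, of which the LIF, IL11 and IL6 calls were lost without 4, 4 and 6 of the 6 arrays in turn (adjusted p up to 0.162). Of 32 interferon-stimulated genes, IRF9 rose 1.43-fold, while IFIT2 was 1.51-fold and IFIH1 1.29-fold lower and IFIT5 fell by 0.26 on the log2 scale (1 rose and 5 fell when adjusted over the list alone). Of these, IFIT2 passed without any single array, and IRF9, IFIH1 and IFIT5 were lost without 3, 5 and 6 of the 6 in turn (adjusted p up to 0.142). Without both arrays numbered 1 there were 1 rise and 1 fall. That list was not called (camera adjusted p = 0.23), but it passed without treated array 3 (adjusted p = 0.0158).

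Genes of antigen presentation were lower in a few members. Of 28 measured members 4 fell and 0 rose, also when adjusted over the list alone. They were the peptide transporter subunit TAP2, 1.38-fold lower, and the immunoproteasome subunits PSMB10, PSMB9 and PSMB8, 1.39-fold, 1.33-fold and 1.31-fold lower. Without both arrays numbered 1, 0 members passed, while the list median was -0.09 (log2) against -0.05 with all arrays. TAP2 passed without any single array, and PSMB10, PSMB9 and PSMB8 were lost without 4, 5 and 3 of the 6 in turn (adjusted p up to 0.102). The list missed the threshold (camera adjusted p = 0.0561) and passed without treated array 2 or 3 (adjusted p = 0.0325 and 0.0310).

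Among 22 immediate early and MAPK feedback genes 3 rose and 2 fell, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.0864). DUSP1, a MAP kinase phosphatase, rose 3.21-fold, IER3 3.14-fold and the stress transcription factor ATF3 2.54-fold, while PHLDA1 was 1.80-fold lower. DUSP5 was 1.41-fold lower, a call lost without 5 of the 6 arrays in turn (adjusted p up to 0.0859). Of 10 EGFR family genes, NRG1 rose 1.30-fold and BTC, at a level of 2.71, was 1.24-fold lower, and both calls were lost without any of the 6 arrays (adjusted p up to 0.158). ERBB2 and ERRFI1 differed by 0.28 and -0.25 without passing, 2 members rose and 2 fell when adjusted over the list alone, and that list was not called (camera adjusted p = 0.83).

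Wnt and Notch genes rose in 4 of 25 measured members and fell in 0, also when adjusted over the list alone. WNT5A, a non-canonical Wnt ligand, rose 1.79-fold, the Notch ligand JAG1 1.73-fold, the Notch co-activator MAML2 1.55-fold and TNFRSF19 1.94-fold, and each passed without any single array. As a list they were called by camera (adjusted p = 0.0114, and adjusted p = 0.13 with an estimated correlation). Of 19 YAP/TAZ targets 6 rose and 2 fell (9 and 3 when adjusted over the list alone), of which 4 rises and 2 falls passed without any single array and 3 rises and 1 fall without both arrays numbered 1. GADD45B rose 2.39-fold, NT5E 1.44-fold and TGFB2 as above, while FJX1 was 1.49-fold and MYOF 1.37-fold lower. That list was called (camera adjusted p = 0.0021, and adjusted p = 0.15 with an estimated correlation).

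The list of NRF2 and detoxification genes, some of which have other known regulators, was lower in part. Of 23 measured members 7 fell, 1 rose and 15 did not pass (9 fell and 1 rose when adjusted over the list alone). After CYP1B1, a known target of the aryl hydrocarbon receptor, the falls with the smallest p were AKR1C1, an aldo-keto reductase, 1.71-fold lower, and TXNRD1, thioredoxin reductase, 1.51-fold lower, while heme oxygenase HMOX1 rose 2.05-fold. The AKR1C genes are close paralogs, so the value of AKR1C1 is uncertain. The list was called by camera (adjusted p = 0.0011, and adjusted p = 0.13 with an estimated correlation), and was not called without the probe sets of shared-sequence suffix (adjusted p = 0.0710).

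Of 27 hypoxia and glycolysis genes 6 fell and 2 rose (7 and 2 when adjusted over the list alone). Of these, 3 falls and 1 rise passed without any single array, and 2 falls and 1 rise without both arrays numbered 1. The prolyl hydroxylase EGLN3 was 1.59-fold, MXI1 1.48-fold and hexokinase HK2 1.42-fold lower, whereas VEGFA rose 1.44-fold and the glucose transporter SLC2A1 1.34-fold (lost without 5 of the 6 arrays in turn, adjusted p up to 0.0896). Camera called the list (adjusted p = 0.0148, and adjusted p = 0.21 with an estimated correlation), and the call was lost without treated array 1 (adjusted p = 0.0838) and without both arrays numbered 1 (adjusted p = 0.0613). Its members lay at a median level percentile of 93.6, and the test did not match on level. Of 25 genes of the unfolded protein and amino acid response 4 rose and 1 fell (10 and 3 when adjusted over the list alone). SESN2 rose 1.48-fold, DNAJC3 1.29-fold, HERPUD1 1.25-fold and the chaperone HSPA5 1.24-fold, while the cystine transporter SLC7A11 was 1.39-fold lower. SESN2 alone of these 5 passed without any single array; DNAJC3, HERPUD1, HSPA5 and SLC7A11 were lost without 5, 5, 6 and 1 of the 6 in turn (adjusted p up to 0.0915), and without both arrays numbered 1 there were 1 rise and 0 falls. As a list they were called by camera (adjusted p = 0.0107, and adjusted p = 0.40 with an estimated correlation), and the call was lost without suffixed probe sets (adjusted p = 0.0646) or with the mean of probe sets (adjusted p = 0.0993). Of 16 cholesterol synthesis genes STARD4 rose 1.21-fold, a call lost without any of the 6 arrays (adjusted p up to 0.162), and 0 passed when adjusted over the list alone. SC5D, HMGCS1 and MSMO1 differed by -0.14, -0.14 and -0.13 without passing, and that list was not called (camera adjusted p = 0.83; median 0.00, mean -0.01).

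**Figure D3:**
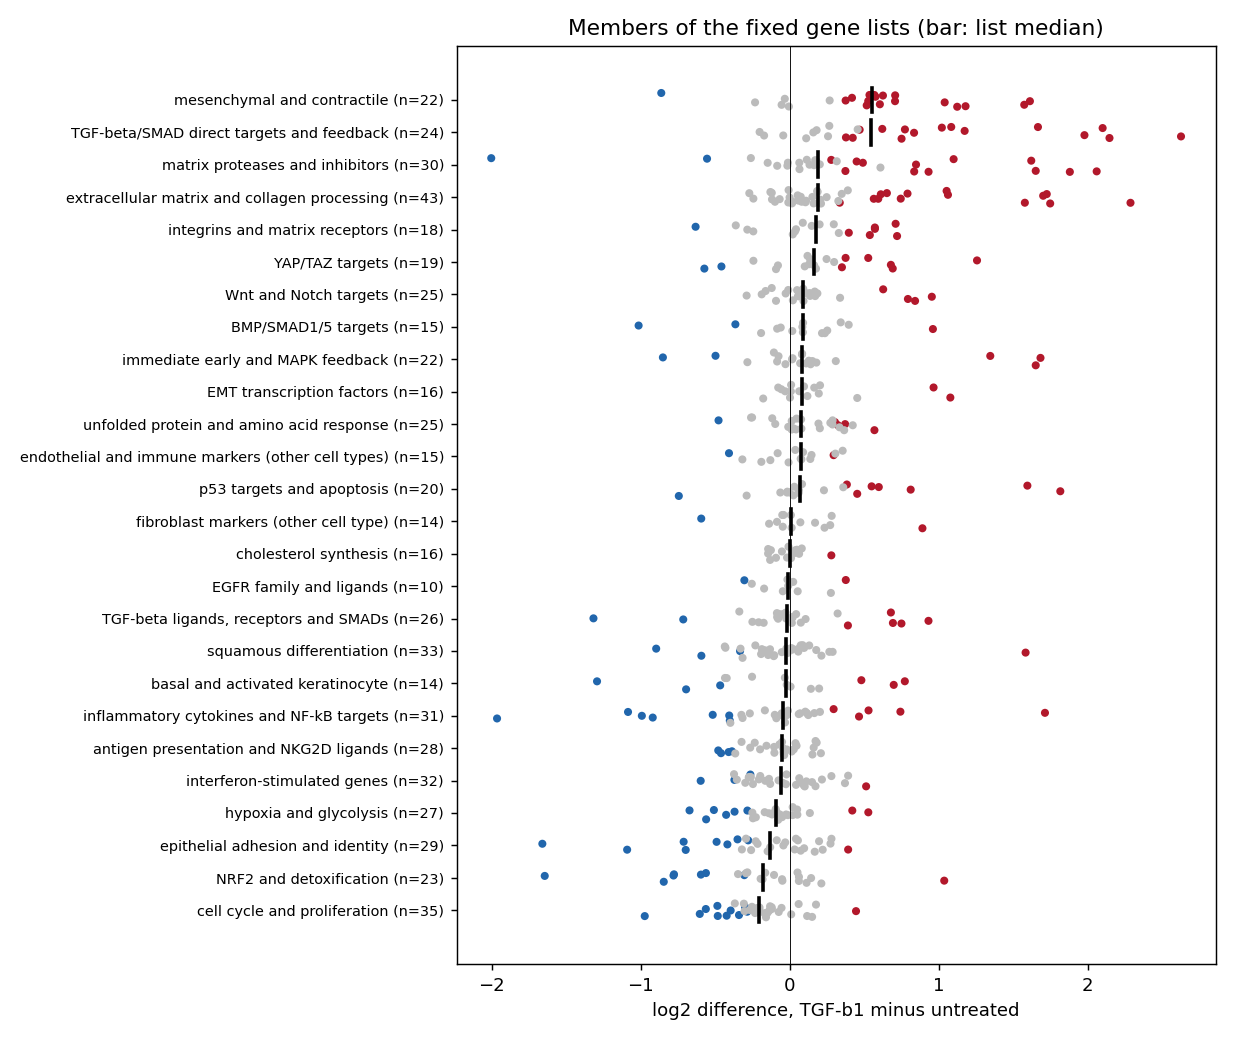
Log2 difference (TGF-β1 minus untreated, horizontal axis) of the measured members of 26 gene lists, 1 point per gene, with the list median as a black bar; red and blue points rose and fell at adjusted p below 0.05 and grey points did not pass. Medians run from -0.20 for cell cycle genes to 0.55 for mesenchymal genes and TGF-β/SMAD targets.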

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

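The tests of RNA quality, of bright probe sets and of second probe sets in this part were chosen after the results were seen. A further 2 kinds of probe sets lie outside the gene comparison. Of 1801 probe sets annotated to several genes, 54 changed with TGF-β1 (28 higher and 26 lower, limma, adjusted p below 0.05 over all probe sets). Of 11721 probe sets with no gene name here, 151 changed (87 higher and 64 lower). They drew attention only because they carry a signal that no comparison above uses.

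The 1680 changed genes are the main pattern. The 6 arrays can be split into 3 and 3 in 10 ways, and 1 of them, the real one, gave as many genes; the highest other split gave 0, but 10 splits are too few for a share under 0.05. A difference in RNA quality between the groups was weighed, since the arrays numbered 1 had the highest 3' over 5' signal. Since calls favour genes with little spread within groups, this was tested on the 1680 genes with the largest differences whatever their p (at least 0.3552 on the log2 scale, 1320 of them called). For the signal to explain the group difference of 0.5153 in the median of these genes per array (falls with sign turned), they would have to follow it with a slope of -6.442. This slope is unstable, since the signal differs little between the groups: without single arrays it ran from -28.86 to 105, nearest to 0 at -2.24 without treated array 1. Within groups, where the signal varied more than between them, the slope was 0.04273 (95% interval 0.01979 to 0.06567), and the interval left out the slope needed also without any single array. Of these genes 95% had slopes between -0.7546 and 0.8822. This argues against RNA quality, as far as these control probe sets measure it. The treatment, which the design names, stays among the open explanations, and 15 of 24 measured TGF-β/SMAD targets rose while 0 fell.

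CDH1 did not pass while mesenchymal genes rose. Saturation of bright probe sets could hide a change at the level of CDH1, yet 5 of the 694 genes at or above its level changed at least 2-fold: FN1, KRT7, TPM1 and TGFBI rose and MAL2 fell (KRT7, TGFBI and MAL2 were chosen after their values were seen). This argues against saturation, with the bound of 5 set after some of these genes had been seen. Whether the choice of probe set matters cannot be told: the other CDH1 probe set differed by -0.14, and its 95% interval (-0.33 to 0.06) lies above the fall of 0.5 set in advance as the bound. That bound was too strict for a probe set at a level of 4.35: of 71 second probe sets of similar level, from genes whose brightest probe set fell by more than 0.5, only 10 fell by as much, with a median of -0.22. A state in which mesenchymal genes rise and CDH1 transcript is kept is a hypothesis that may fit these values, and CDH1 protein was not measured here.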

How the results depend on the processing

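The alternatives without both arrays numbered 1 and with the 3' to 5' covariate were chosen after seeing the data. The number of changed genes was 1680. It was 995 without probe sets of shared-sequence suffix, where 17098 genes were tested, 2629 with a trended robust variance, 327 with treat against a fold of 1.2, 628 without both arrays numbered 1, and 766 to 1319 when single arrays were left out, where fewer samples enter the fit. Under the other settings it lay between 1280 and 2296. Genes changed at least 2-fold numbered 83 to 130. The replicate block gave 1280 genes, 124 of them changed at least 2-fold, and 14 lists. The genes called were in part different ones. Of the 1680 calls, 1194 were kept with the block and 1171 with the mean of probe sets. Without suffixed probe sets, 945 of the 1410 that could be tested were kept. The sign was the same in 1680, 1679 and 1341 of them. Of 26 lists 14 were called, 11 to 16 when single arrays were left out, and 3 with an estimated correlation (TGF-β/SMAD targets, mesenchymal genes and extracellular matrix). With that correlation adjusted p was 0.15 for EMT factors, 0.39 for epithelial adhesion, 0.0697 for proteases, 0.13 for integrins, 0.0721 for cell cycle, 0.21 for hypoxia, 0.40 for the unfolded protein response, 0.13 for NRF2, 0.15 for p53, 0.13 for Wnt and Notch, and 0.15 for YAP/TAZ. Adjusted p was 0.0536 for hypoxia among genes above the median level. With the mean of all probe sets it was 0.0451 for BMP targets, 0.0133 for immediate early genes and 0.0993 for the unfolded protein response. Without suffixed probe sets it was 0.0330 for interferon genes, 0.0646 for the unfolded protein response and 0.0710 for NRF2. It was 0.0345 for antigen presentation with the covariate, and 0.0532, 0.0613 and 0.0613 for EMT factors, epithelial adhesion and hypoxia without both arrays numbered 1. Rank-based camera gave 0.0895 for EMT factors and 0.0581 for epithelial adhesion. The fry test asks whether the members of a list shift in a shared direction, and not whether they differ from the other genes. It gave 0.0419 for inflammatory and 0.0051 for immediate early genes. With single arrays left out the camera adjusted p ran from 0.0183 to 0.0562 for EMT factors, 0.0032 to 0.0550 for epithelial adhesion, 0.0065 to 0.0838 for hypoxia, 0.0310 to 0.25 for antigen presentation and 0.0158 to 0.78 for interferon genes. The cause of these differences between settings was not tested. Camera compares a list with all other genes, and none of the 26 lists was matched on level. The median difference was -0.0027 over all genes and -0.022 among those above the median level. The 4 lists called lower had median level percentiles of 93.6 for hypoxia, 90.9 for cell cycle, 81.1 for NRF2 and 77.7 for epithelial adhesion. Part of their shift can come from level. Among genes above the median level, only the hypoxia call was lost.

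Some lists turned direction while passing in neither setting. The cholesterol list did so with adjusted p of 0.9683 after repeated quantile normalisation, 0.9659 above the median level, 0.7852 with the mean of probe sets and 0.6759 without suffixed probe sets. The EGFR list did so at 0.6086 above the median level, 0.7452 above the lowest quartile of levels and 0.8278 with the mean of probe sets, and without treated array 2, where its adjusted p with single arrays left out ran from 0.7205 to 0.9721. Without suffixed probe sets the ligand and receptor, inflammatory and immediate early lists turned at 0.7992 each and the fibroblast list at 0.8791, and the ligand and receptor list turned at 0.9445 with rank-based camera. Of 128 genes named by the rule 91 kept their side of the threshold in every setting that tested them, and 82 of them also kept their direction. Some genes were tested in only 15 or 16 of 17 settings. For example, CXCL8, CYP1B1, DUSP1 and HS3ST1 have only suffixed probe sets and were not tested without these. Without suffixed probe sets 5 called genes turned direction and did not pass, each then represented by a dimmer probe set, at log2 differences of 0.0384 for SERPINB13, -0.0793 for TGFB1, 0.0148 for KLK10, 0.1236 for CXCL2 and -0.1463 for HERPUD1. Genes that passed in neither setting turned to -0.0966 for TGFBR1, 0.1196 for SMAD2, 0.2883 for SC5D and -0.0730 for CD163 there. With the mean of probe sets they turned to -0.04885 for TGFBR1, 0.0044 for SMAD4, -0.0400 for CDH1 and 0.0717 for SC5D. After repeated quantile normalisation TGFBR2 was at 0.0002561, ZEB1 at -0.0111 and ZEB2 at -0.0003125, and ZEB1 was at -0.0649 with array weights and -0.0296 without both arrays numbered 1. With single arrays left out TGFBR1 ran from -0.0093 to 0.0433, TGFBR2 from -0.0505 to 0.0038, CDH1 from -0.0353 to 0.1159, ZEB1 from -0.1374 to 0.1090 and ZEB2 from -0.0572 to 0.0698. The 3' to 5' difference of -0.08 ran from -0.227 to 0.0432, turning direction without untreated array 1 (0.0432) or treated array 2 (0.0049). Signal over background could not be judged per probe.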

Other observations

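All tests in this part, and the gene families and genes they use, were chosen after the results were seen. Some genes for making ribosomes were lower in treated cells. Of 35 ribosome biogenesis genes 13 fell and 0 rose, 34 had a negative difference, and the median was -0.28 (log2); POLR1B, a subunit of RNA polymerase I, was 1.68-fold lower, the helicase gene DDX21 1.47-fold lower and WDR12 1.46-fold lower. Of 75 mitochondrial ribosomal protein genes 6 fell and 0 rose, 67 had a negative difference and the median was -0.14, with MRPL46 1.32-fold, MRPS6 1.30-fold and MRPL19 1.28-fold lower. Of 23 protein-coding genes with a NUP symbol, nucleoporins and their paralogs, 6 fell and 0 rose, with NUP35 1.52-fold and NUP88 1.37-fold lower. Of 58 cytosolic ribosomal protein genes and their paralogs 0 fell and 1 rose, RPS27L, by 0.59 (log2), with a median of -0.0822 (camera adjusted p = 4.0e-04, and adjusted p = 0.0858 with an estimated correlation). This median lay at the lower edge of the middle 95% of medians of random lists matched on level (-0.0823 to -0.0042), at percentile 2.61. Of these 58 genes 52 had a negative difference. Without both arrays numbered 1 the medians were -0.27, -0.14, -0.20 and -0.09, and 2, 0, 2 and 0 genes fell. After repeated quantile normalisation they were -0.27, -0.12, -0.18 and -0.09, and after median centring -0.28, -0.14, -0.19 and -0.08, while 4 and 3 mitochondrial ribosomal protein genes fell under these scalings. The 3 lists with falls were called by camera at the preset correlation (adjusted p at most 9.2e-07 over 6 families) and not with an estimated correlation (adjusted p = 0.0626 for each).

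Clade B serpins, intracellular protease inhibitors of epithelia, fell in 6 of 11 measured genes and rose in 1. SERPINB13 and SERPINB1 were 5.46-fold and 1.77-fold lower, while SERPINB5, which encodes maspin, was 1.37-fold higher (camera adjusted p = 5.6e-04, and adjusted p = 0.0658 with an estimated correlation). Without both arrays numbered 1, 3 fell and 0 rose. Of 9 pregnancy-specific glycoprotein genes 4 rose and 0 fell, with PSG1 at 1.40-fold (camera adjusted p = 1.1e-05, and adjusted p = 0.0658 with an estimated correlation). These genes are near-identical copies, so their probe sets may report shared transcripts. Among them 1 rose without both arrays numbered 1, an alternative under which the number of changed genes overall was 628. Their median was 0.30 (log2) there, against 0.23 with all arrays.

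The lower mitochondrial ribosomal protein genes were weighed against 2 technical explanations. Random lists matched on expression level, drawn 10000 times, had medians between -0.10 and 0.01 in their middle 95%, with a midpoint of -0.049. The observed -0.14 lay below this range. This argues against a shift of all genes of that level as the whole explanation, although such a shift can account for part. The range does not allow for genes of 1 family varying together. For the 3' to 5' signal to explain them, they would have to follow it with a slope of 1.753 (from -29.09 to 9.383 without single arrays, nearest to 0 at 0.5297 without treated array 1), and within groups the slope was -0.1037 (95% interval -0.2313 to 0.02396), which argues against RNA quality as far as this signal measures it. The interval left out the slope needed also without any single array. Lower MYC-linked ribosome production is a candidate explanation: MYC fell, and the separate ribosome biogenesis list had a median of -0.28 against a matched range from -0.11 to 0.04. That list was written after a few such genes had been seen to fall, and MYC protein was not measured. A slower cell cycle would predict the same and was not tested apart. Of 35 cell cycle genes 10 were lower and 1 higher.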
